A study of Mus musculus with 6 samples.

How the data were processed

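Total RNA was measured on 6 Affymetrix arrays, 1 per mouse: 3 wild type mice and 3 MYB knockdown mice. All were males, 4 weeks old, on the C57BL6 strain, per the labels. The cells were sorted by flow cytometry from bone marrow as Kit-positive, CD11b-positive and lineage-low, a gate that the labels abbreviate K11bL. RNA was extracted with Trizol and labelled with a whole-transcript kit and biotin, per the labels' protocols, so a probe set samples the length of a transcript and not only its 3' end. The labels do not say how the expression of Myb was lowered.

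The deposited table holds 1 log2 value per probe set and array, made by the authors. Per the submitters' processing notes, Affymetrix Expression Console and limma were used; their versions, their roles, and the method of background correction, normalization and summarisation are not given in the sources used here. The log2 scale was read from the values, which lay between 1.83 and 13.3 on all arrays with array medians between 5.87 and 5.99, and no centring of genes was seen. Arrays carry no read depth: the precision is limited by the number of arrays, and a bright probe set can understate a change. The sources used here give no scan date or other batch.

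Of the 35556 probe sets, 21789 had 1 gene symbol in the platform annotation, 1621 had several and 12146 were not in the annotation table used here. Of those with 1 symbol, 21698 were matched by gene number to the RefSeq annotation of GRCm38.p6, and 0 symbols were changed. That annotation was used only for names and for which genes neighbour each other. Only probe sets with 1 symbol were used. Where a gene had several (999 of 19938 genes), the probe set of the highest mean over all 6 arrays was taken. Genes whose mean over all 6 arrays lay in the lowest 30% were left out, which left 13956 genes.

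From these values the knockdown was compared with the wild type in limma 3.58.1 (R 4.3.3), with lmFit and eBayes with a trend, no covariates, and the Benjamini-Hochberg adjustment over all genes tested, with a threshold of 0.05. Every adjusted p of a gene comes from this fit. Differences are knockdown minus wild type on the log2 scale with the standard error (SE) of the fit, and n was 3 mice per group throughout. The labels name separate mice, so the spread is that between animals. On simulated data with the means and spreads of these 13956 genes, with 50 genes changed at each size, the same fit recovered 34% of the genes changed by 0.5 on the log2 scale, 78% of those changed by 1, 96% of those changed by 2 and 100% of those changed by 3. Of its 156 calls, 2 were unchanged genes. The simulation drew each gene independently, with the same spread in both groups and no array that stood apart. It also changed far fewer genes than were called in the real data, so its rates need not hold for them.

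Before the data were examined, 29 gene lists were written from textbook knowledge: lineages that the bone marrow or the gate could hold, cell cycle, survival, cytokine signalling and stress. The sort markers and the Y-linked genes with Xist were read as values only. The other 27 were tested with camera of limma, two-sided, with the preset correlation of 0.01 between genes, adjusted over the 27 lists. Camera compares a list's genes with all other genes. With a correlation estimated from these 6 arrays, camera called 0 lists after adjustment and 6 at an unadjusted p under 0.05. The test fry, which asks whether a list's own genes move one way on balance, called 10. Members of a list are counted as changed from the fit over all genes, and beside it after an adjustment over the list alone. Spry2 and the list of the IL-3 pathway were chosen with knowledge of published work on Myb knockdown mice, which may include these arrays, so they are not independent evidence of their direction.

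The genes named were fixed by a rule, also before the data were examined: Myb, the 12 largest rises and the 12 largest falls among called genes whose groups did not overlap, up to 4 members of smallest p in each list, and Spry2, Kit and Itgam. Predicted genes, olfactory receptors and small RNAs were passed over. Genes named outside the rule are marked as such.

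The alternatives were the replicate number as a block, each array left out in turn, quantile normalization, median centring, no filter on dim genes or a filter at 50%, the mean of a gene's probe sets, eBayes without the trend or robust, array weights, an adjusted p of 0.1, a minimum change of 1.5-fold, and for lists the estimated correlation and fry. The replicate numbers name different mice. Chosen after seeing the data were the counts of list members with each array left out and the p53 list without Perp. Some symbols of the lists had no probe set of their own and are not analysed here.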

Results

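Gene expression was measured in a myeloid progenitor fraction of the bone marrow, sorted as Kit-positive, CD11b-positive and lineage-low, from 3 wild type mice and 3 mice with a knockdown of Myb, a transcription factor of haematopoietic progenitors. Kit is the receptor of stem cell factor and marks progenitors, and CD11b (Itgam) is an integrin of myeloid cells. The title of the series calls these cells myeloproliferative, and the design implies a single comparison, knockdown against wild type. The array medians lay between 5.87 and 5.99 on the log2 scale. The correlation over all probe sets was between 0.993 and 0.995 among the 3 wild type arrays and 0.994 between knockdown mice 1 and 2. Knockdown mouse 3 stood apart, with correlations of 0.977 and 0.984 with the other 2 knockdown arrays.

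Myb itself was lower in each knockdown mouse. Its log2 value was 11.46 ± 0.002 (SD, n = 3) in wild type and 11.16 ± 0.09 (SD, n = 3) in knockdown, a fall by 0.30 ± 0.06 (SE) or 1.23-fold (adjusted p = 0.0196). Its probe set was brighter than that of 98.98% of genes, and neither the position of its probes in the transcript nor the nature of the knockdown is given in the sources used here, so the 1.23-fold difference may not be the size of the knockdown. The call was not kept under every setting. Without wild type mouse 1, 2 or 3 or knockdown mouse 2 the adjusted p was 0.0967, 0.0894, 0.0926 and 0.0776. The differences then lay between -0.30 and -0.26. A fit without 1 array has fewer mice, so a lost call need not be due to the mouse left out. On all arrays the adjusted p was 0.074 after median centring (difference -0.23) and 0.0662 without the trend of eBayes. Of the sort markers, Kit differed by -0.27 ± 0.08 (adjusted p = 0.06) and Itgam by -0.39 ± 0.17 (adjusted p = 0.202). Ly6g, a neutrophil surface antigen, differed by -1.50 ± 0.57 (adjusted p = 0.141) and Il7r, the IL-7 receptor of lymphoid progenitors, by -0.60 ± 0.17 (adjusted p = 0.0559). Each passed the test with some arrays left out: Kit without knockdown mouse 3 (adjusted p = 0.0147), Itgam and Ly6g without knockdown mouse 1 (0.0239 and 0.0369), and Il7r without wild type mouse 1 (0.0465), knockdown mouse 1 (0.0408) or knockdown mouse 3 (0.0447). With array weights on all arrays all of them passed (adjusted p = 0.00423 for Kit, 0.0318 for Itgam, 0.0132 for Ly6g and 0.00513 for Il7r). Kit also passed after quantile normalization (0.0405) and with a filter at 50% (0.0497). The Y-linked genes Kdm5d, Eif2s3y and Uty had wild type means of 7.86, 9.12 and 8.61 and knockdown means of 7.80, 9.01 and 8.31, and Xist lay at 3.95 and 3.77.

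Between the groups 1619 of 13956 genes changed, of which 854 rose and 765 fell. At least a 2-fold change was seen for 116 of the genes that rose and for 213 of those that fell. The groups did not overlap for 34.3% of all genes tested, where chance gives 10% on average. Genes on the same arrays vary together, so the 2 shares are not a test against chance. After median centring of the arrays 1433 genes rose and 593 fell, so the split between rises and falls depends on the scaling. The counts also changed with 1 array left out. Without knockdown mouse 3, 2391 rose and 1401 fell. Without wild type mouse 1, 2 or 3 or knockdown mouse 2 the rises numbered 298, 309, 357 and 428. The falls were then 365, 381, 389 and 481. These lower counts come with fewer mice and need not be due to the mouse left out.

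Many of the largest falls were in genes of granulocytes, several of them over 10-fold. Chil3, a chitinase-like protein of myeloid cells, fell by 5.68 ± 0.53 (51.2-fold, adjusted p = 0.000424). Its knockdown values were 6.97, 5.03 and 4.51, the last close to the lower quartile of that array (4.46), and without knockdown mouse 1 Chil3 fell by 6.41, so the size of its fall is uncertain. Tfec, a transcription factor of the MiT family, fell by 4.41 ± 0.21 (21.3-fold). Fcnb, a ficolin of neutrophil granules, fell by 4.25 ± 0.15 (19.0-fold), and Elane, neutrophil elastase, by 3.69 ± 0.08 (12.9-fold, adjusted p = 2.66e-07). Of the eosinophil genes, Epx, eosinophil peroxidase, fell by 4.14 ± 0.29 and Ear6, an eosinophil-associated ribonuclease, fell by 3.96 ± 0.35. Mcpt8, a protease of basophils, fell by 3.31 ± 0.16, and Prss34, another, fell by 3.47 ± 0.29. The remaining genes among the 12 largest falls were Clec4b2 (-3.91 ± 0.26), a lectin receptor, Ifi209 (-3.71 ± 0.16), an interferon-inducible gene, Chil1 (-3.55 ± 0.22), another chitinase-like protein, and Camp (-3.36 ± 0.36), the cathelicidin of neutrophil granules. Ear6, Clec4b2 and Ifi209 belong to families of close relatives, and whether their probes separate the members was not tested here.

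The largest rises included platelet genes and a cytokine receptor. Ppbp, a chemokine of platelet granules, rose by 3.50 ± 0.20 (11.3-fold, adjusted p = 4.2e-05), and Thbs1, thrombospondin, by 2.62 ± 0.27 (6.13-fold). Perp, a p53-induced membrane protein, rose by 3.47 ± 0.18 (11.1-fold); it lies within 20 Mb of Myb on the same chromosome. Mmp8, the neutrophil collagenase, rose by 3.26 ± 0.36, against the fall of most neutrophil genes. Gpr174, a receptor for lysophosphatidylserine, rose by 2.88 ± 0.18, Alox15, a lipoxygenase, by 2.85 ± 0.38, and Ccr1, a chemokine receptor, by 2.35 ± 0.22. S100a6, a calcium-binding protein, rose by 2.32 ± 0.15, Wfdc17 by 2.15 ± 0.20, Vldlr, a lipoprotein receptor, by 2.08 ± 0.27, and Cd200r4 by 2.06 ± 0.19. The wild type values of Gpr174 (4.32, 4.46 and 4.92) and Cd200r4 (4.34, 3.85 and 4.45) were dim, with all but the last of Gpr174 under the lower quartiles of their arrays (4.55, 4.58 and 4.55), so the size of both rises, and with it their place among the largest, is uncertain. Csf2rb2, the beta chain of the IL-3 receptor found in mice, rose by 2.13 ± 0.11 (4.37-fold, adjusted p = 2.45e-05).

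**Figure D1:**
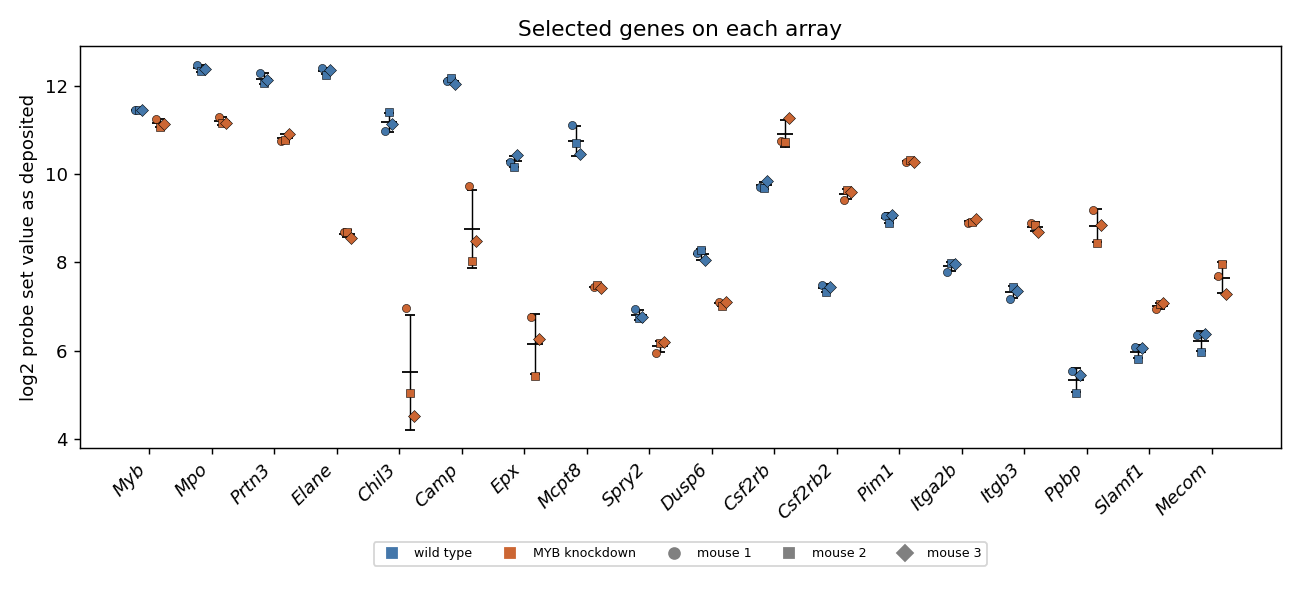
Log2 probe set values as deposited (vertical axis) of 18 named genes on each of the 6 arrays, wild type in blue and MYB knockdown in orange, with a marker shape per mouse number and bars for the mean ± SD of 3 mice. The 3 knockdown values lie below the 3 wild type values for Myb, the granule genes and Spry2, and above them for Csf2rb, Csf2rb2, Pim1, Itga2b, Itgb3, Ppbp, Slamf1 and Mecom.

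Genes of primary granules, made at the promyelocyte stage, were lower as a group: 9 of 10 measured members fell (10 adjusted over the list alone), with a median difference of -1.08. Beside Elane, Mpo, myeloperoxidase, fell by 1.20 ± 0.07, Prtn3, proteinase 3, by 1.35 ± 0.08 and Ms4a3 by 0.97 ± 0.07. Camera gave an adjusted p of 7.05e-12 for this list, and adjusted p = 0.123 with an estimated correlation. Of 23 genes of secondary granules and mature neutrophils, 12 fell and 3 rose (16 and 4 adjusted over the list alone), with a median of -0.76 (adjusted p = 1.49e-07, and adjusted p = 0.276 with an estimated correlation). Olfm4, a granule glycoprotein, fell by 2.56 ± 0.19 and S100a8, a subunit of calprotectin, by 1.45 ± 0.15. Of 9 eosinophil genes 5 fell and 1, Alox15, rose (7 and 1 adjusted over the list alone), with a median of -1.28 (adjusted p = 5.98e-06, and adjusted p = 0.307 with an estimated correlation). Prg2, a protein of eosinophil granules, fell by 2.63 ± 0.30, and Prg3, its relative, fell by 2.22 ± 0.15.

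The list of genes that earlier work names as activated by MYB shares Mpo, Elane, Prtn3 and a further member with the primary granule list. Of its 16 measured members 6 fell and 2 rose (7 and 4 adjusted over the list alone), the mean difference was -0.47 and the median -0.05 (adjusted p = 0.0233, and adjusted p = 0.216 with an estimated correlation). Gfi1, a transcriptional repressor needed for neutrophils, fell by 1.49 ± 0.12. Without knockdown mouse 3 the list's adjusted p was 0.0647 and 4 members rose, and without any 1 wild type mouse or knockdown mouse 2, 1 rose.

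Genes of stem cells and early progenitors were higher: 13 of 21 measured members rose (15 adjusted over the list alone), with a median of 0.47 (adjusted p = 3.06e-08, and adjusted p = 0.123 with an estimated correlation). Mecom, a transcription factor of stem cells, rose by 1.43 ± 0.19, Slamf1 (CD150) by 1.04 ± 0.11, Mllt3 by 0.85 ± 0.10 and Hlf by 0.81 ± 0.11. A second, dimmer probe set of Mecom differed by 0.34. Of the list 7 genes rose without wild type mouse 1 and 8 without wild type mouse 2. Myct1, a member that rose by 0.68 ± 0.12 (named after its values were seen), lies within 20 Mb of Myb. Genes of megakaryocytes and platelets were higher as well, with 10 of 17 that rose (12 adjusted over the list alone) and a median of 1.02 (adjusted p = 5.94e-09, and adjusted p = 0.116 with an estimated correlation). Itgb3 and Itga2b, the chains of the platelet fibrinogen receptor, rose by 1.48 ± 0.11 and 1.02 ± 0.10, and Plek, a kinase substrate of platelets, by 1.04 ± 0.10. The mean shift of this list was between 0.92 and 1.08 in each knockdown mouse.

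The IL-3, GM-CSF and JAK-STAT5 list, chosen with knowledge of published work and so not independent evidence, was higher, with 7 of 24 members that rose (9 adjusted over the list alone) and a median of 0.21 (adjusted p = 0.000822, and adjusted p = 0.123 with an estimated correlation). Beside Csf2rb2, the shared beta chain Csf2rb rose by 1.17 ± 0.15, Pim1, a kinase gene induced by STAT5, by 1.29 ± 0.09 and Socs3, a feedback inhibitor, by 0.89 ± 0.11. A second, dimmer probe set of Socs3 differed by -0.01. Without knockdown mouse 3, 2 members fell. Csf2rb and Csf2rb2 are close relatives, and cross-hybridization between them was not tested. Of 17 Sprouty, Spred and ERK feedback genes 2 rose and 2 fell (2 and 3 adjusted over the list alone), and the list was not called (median 0.10, adjusted p = 0.935). Without knockdown mouse 3, 4 of them fell, and without any 1 wild type mouse or knockdown mouse 2, 1 rose. Spry2, an inhibitor of receptor tyrosine kinase signalling, fell by 0.71 ± 0.11 (1.64-fold, adjusted p = 0.0049), and Dusp6, a phosphatase of ERK, by 1.11 ± 0.11. Ccnd1, cyclin D1, rose by 1.01 ± 0.13.

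Genes of the nucleolus and of MYC-driven growth were higher in 21 of 21 measured members, of which 8 rose in the test over all genes (15 adjusted over the list alone), with a median of 0.35 (adjusted p = 1.18e-06, and adjusted p = 0.276 with an estimated correlation). The count changed with 1 array left out. Without knockdown mouse 3, 20 rose. Without wild type mouse 1, 2 or 3 the count was 0, 1 and 2. It was 2 without knockdown mouse 2 and 5 without knockdown mouse 1. In the fits without a wild type mouse, 14, 11 and 14 members were still higher at an unadjusted p under 0.05 by limma. Camera called the list each time. Bop1, a factor of ribosome assembly, rose by 0.67 ± 0.12 and Srm, spermidine synthase, by 0.47 ± 0.08; without wild type mouse 1 their adjusted p was 0.0532 and 0.0527, and without wild type mouse 2 that of Bop1 was 0.0533. Of 15 p53 target genes 6 rose (7 adjusted over the list alone), with a median of 0.31 (adjusted p = 0.000224, and adjusted p = 0.156 with an estimated correlation). Perp had the largest rise of the list, and Sesn1 and Zmat3 rose by 0.60 ± 0.09 and 0.65 ± 0.11. Without Perp the list's adjusted p was 0.00229. Of the p53 target genes, 3 rose without wild type mouse 1.

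Of 15 B lymphoid genes 6 fell and 1 rose (7 and 1 adjusted over the list alone), with a median of -0.50 (adjusted p = 3.97e-05, and adjusted p = 0.222 with an estimated correlation). Igll1, part of the surrogate light chain, fell by 2.06 ± 0.33, Dntt, the terminal transferase of lymphoid progenitors, by 1.40 ± 0.21 and Bank1 by 0.79 ± 0.13. Without wild type mouse 2 or 3 or knockdown mouse 2, 3 B lymphoid genes fell, and the rise, of Cd22, was not called without any 1 wild type mouse. The labels do not name the lineage markers of the gate. Of 14 erythroid genes 2 rose (3 adjusted over the list alone), with a median of 0.33 (adjusted p = 0.0245, and adjusted p = 0.699 with an estimated correlation). The mean shift of the erythroid list was 0.35, -0.16 and 0.81 in knockdown mice 1, 2 and 3, and its adjusted p was 0.417 without knockdown mouse 3, 0.0754 without knockdown mouse 1 and 0.0718 without wild type mouse 1. It was 0.0675 after quantile normalization, 0.0681 after median centring, 0.122 with a filter at 50%, 0.653 with array weights and 0.262 with fry. Without knockdown mouse 1, 1 erythroid gene rose. Without wild type mouse 1 or 3, limma called 0 erythroid genes, and 5 of the 14 had an unadjusted p under 0.05 on all arrays. Of 22 immediate early genes 4 rose and 1 fell (5 and 1 adjusted over the list alone), with a median of 0.29 (adjusted p = 0.0245, and adjusted p = 0.694 with an estimated correlation). Its adjusted p was 0.214 without knockdown mouse 3 and 0.0902 without wild type mouse 3, and the list's adjusted p was 0.062 after median centring, 0.122 with a filter at 50%, 0.0704 with array weights and 0.124 with fry. Of its genes 2 rose without wild type mouse 1 and 1 without wild type mouse 2. Without wild type mouse 3 limma called 0 of them higher. The fall, of Rhob, was not called without wild type mouse 1 or 3 or knockdown mouse 1 or 2.

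The lists of the other lineages were not called. Of 21 monocyte and macrophage genes 4 rose and 4 fell (4 and 5 adjusted over the list alone; adjusted p = 0.235). F13a1, coagulation factor XIII of monocytes, fell by 2.84 ± 0.34 and Mpeg1, perforin-2, by 0.98 ± 0.13. Cd68, a lysosomal glycoprotein, rose by 1.23 ± 0.18 and Fcgr1, the high-affinity IgG receptor, by 0.76 ± 0.10. Without knockdown mouse 1 this list was called down (adjusted p = 0.0275) and 7 of its genes fell, and without wild type mouse 1 or 3 or knockdown mouse 2, 2 rose. Of 18 dendritic cell and MHC class II genes 4 rose and 2 fell (4 and 2 adjusted over the list alone; adjusted p = 0.349), among them Cd209a, a lectin, with a rise by 1.64 ± 0.21, and Tcf4, a transcription factor of plasmacytoid dendritic cells, with a rise by 0.79 ± 0.10. Without knockdown mouse 3, 4 fell, without wild type mouse 1 or 2, 2 rose, and the falls, of Xcr1 and of Clec9a (named after its values were seen), were not called without wild type mouse 2 or 3 or knockdown mouse 2. Of 13 mast cell and basophil genes 3 rose and 4 fell (3 and 4 adjusted over the list alone; adjusted p = 0.537), with a median of 0.11 and a mean of -0.21. Ifitm1 rose by 1.61 ± 0.14, while Hdc, histidine decarboxylase, fell by 1.76 ± 0.17. Of these genes 1 rose without wild type mouse 2 or 3 or knockdown mouse 2. Of 11 T and NK genes 2 rose (3 adjusted over the list alone; adjusted p = 0.167), one of them Klrd1 by 1.42 ± 0.19, and without any 1 wild type mouse, 1 rose. Of 12 stromal and endothelial genes 2 fell (2 adjusted over the list alone; adjusted p = 0.465), one of them Vcam1, an adhesion molecule, by 3.00 ± 0.24. Without wild type mouse 1 or 3 or knockdown mouse 1, 1 fell, and without knockdown mouse 3, 1 rose.

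Few cell cycle genes passed the test. Of 23 S phase genes 1 rose (1 adjusted over the list alone; median 0.05, adjusted p = 0.454), and without knockdown mouse 3, 5 rose. The rise, of Ccne1, was not called without any 1 wild type mouse. Of 24 genes of the G2 and M phases 1, Cdc25b, rose by 0.51 ± 0.13 over all genes (median -0.05, adjusted p = 0.514). With limma 0 passed adjusted over the list alone, where 2 had an unadjusted p under 0.05, and fry gave the list an adjusted p of 0.87. Without knockdown mouse 3, 2 rose, and without any other single array 0 did; Aurkb differed by 0.16 ± 0.09 and Cenpe by -0.36 ± 0.16. Of 14 cyclin-dependent kinase inhibitors and G1 cyclins, Ccnd1 rose and Cdk6, a kinase of G1, fell by 0.43 ± 0.07 (1 and 1 adjusted over the list alone; median -0.05, mean 0.02, adjusted p = 0.757). Of 13 BCL2 family genes 1 rose and 1 fell (1 and 1 adjusted over the list alone; adjusted p = 0.514), with 2 that rose without knockdown mouse 3. The rise, of Pmaip1, was not called without any 1 wild type mouse, and the fall, of Bid, was not called without any 1 array other than knockdown mouse 3, while Bcl2 differed by 0.24 ± 0.09 (adjusted p = 0.117).

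Of 37 haematopoietic transcription factors 10 rose and 4 fell (15 and 4 adjusted over the list alone; median 0.24, adjusted p = 0.0752). Id1, an inhibitor of helix-loop-helix factors, rose by 0.65 ± 0.10 and Ets1 fell by 1.11 ± 0.15. The list was called up without knockdown mouse 2 (adjusted p = 0.0123) and without the filter on dim genes (adjusted p = 0.0188). Without wild type mouse 1, 2 or 3, 3, 3 and 5 rose, and without wild type mouse 1 or 3, 2 fell. Of 26 haematopoietic cytokine receptors 2 rose and 4 fell (6 and 7 adjusted over the list alone; median 0.05, camera direction down, adjusted p = 0.517), and without knockdown mouse 3, 6 rose and 11 fell. Lifr, the receptor of leukaemia inhibitory factor, rose by 2.05 ± 0.14, while Ifngr1, the interferon gamma receptor, which also lies within 20 Mb of Myb, fell by 0.88 ± 0.08 and Csf3r, the receptor of G-CSF, by 0.58 ± 0.08. Of 19 interferon-stimulated genes 1, Ifi27l2a, rose by 0.73 ± 0.12 (1 adjusted over the list alone; adjusted p = 0.465); without knockdown mouse 3, 2 rose and 1 fell. Of 19 adhesion and integrin genes 3 rose and 2 fell (4 and 2 adjusted over the list alone; median -0.03, mean 0.02, adjusted p = 0.862), where Cd63, a granule membrane protein, fell by 1.63 ± 0.19 and 1 gene fell without any 1 wild type mouse or knockdown mouse 2. Of 10 heat shock genes 9 were higher with a median of 0.17; limma called 0 of them (adjusted p of the list = 0.145), 3 had an unadjusted p under 0.05, 0 passed when adjusted over the list alone, fry gave the list an adjusted p of 0.0602, and without knockdown mouse 1, 1 rose, while without knockdown mouse 3, 6 rose and the list was called (adjusted p = 0.0337), as it was with array weights (adjusted p = 0.0325).

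**Figure D2:**
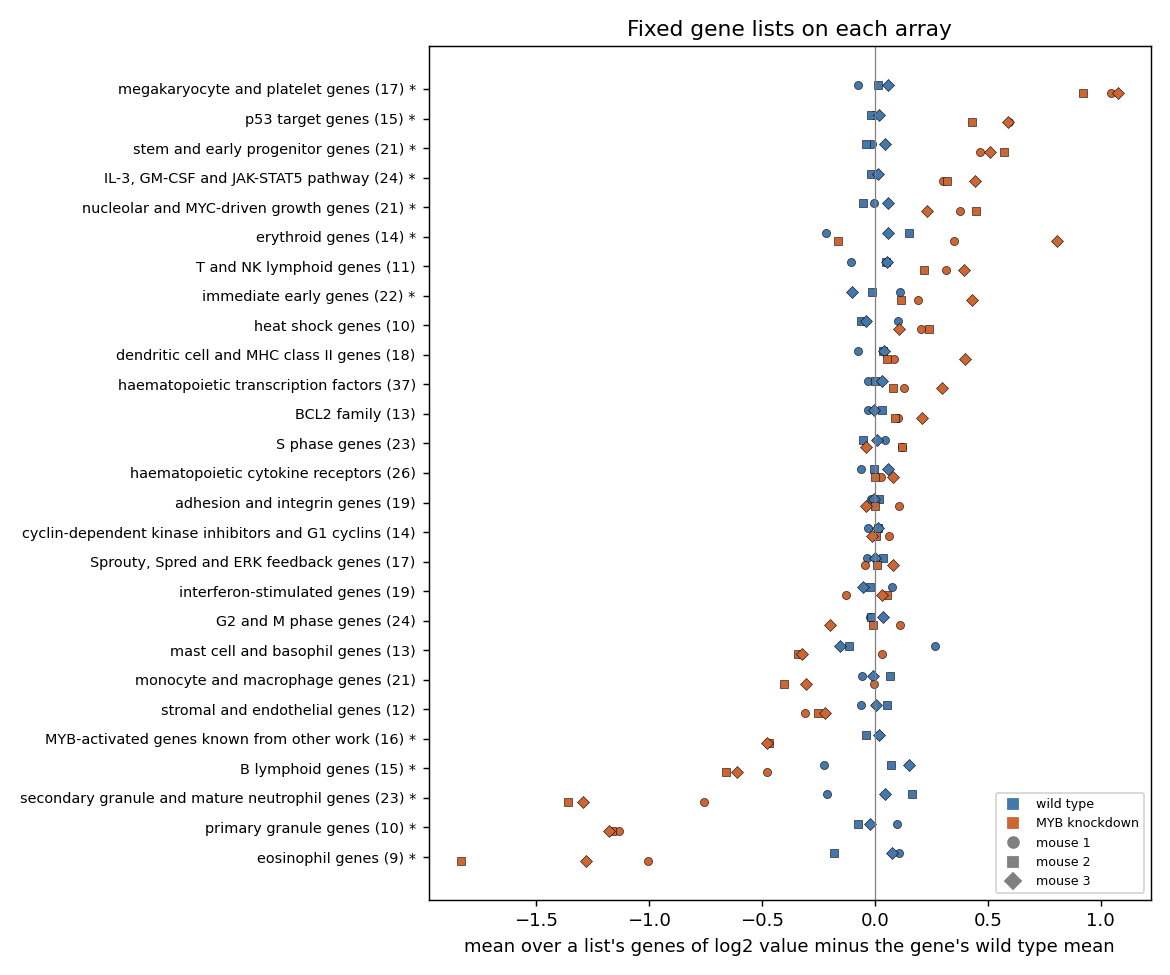
Mean over the measured genes of each of the 27 fixed lists (number of genes in parentheses) of the log2 value minus the gene's wild type mean (horizontal axis), 1 point per array, wild type in blue and MYB knockdown in orange, with a marker shape per mouse number. Lists called by camera at an adjusted p under 0.05 carry an asterisk; the eosinophil and granule lists lie lowest and the megakaryocyte list highest in the knockdown mice, and the erythroid list is spread from -0.16 to 0.81.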

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

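Chosen only after the result was seen were the member counts of the lists with each array left out and the p53 list without Perp; the other alternatives were planned. None of the 1619 calls changed sign, where the gene was tested, under any of the 15 refits with another block, array set, scaling, filter, probe set rule or variance model. Most of these refits could not have changed a sign. The groups did not overlap for any of the 1619, so leaving out or weighting arrays keeps the sign. The block, the filter and the variance model keep the difference itself. Only another scaling or another probe set for a gene could have changed a sign. Of the 90 named genes called besides Myb, 63 were called under all 15, and 6 more wherever they were tested, being below the filter on dim genes in some. In 30 cases a list's count of rises or falls went to 0 by limma with 1 array left out, where between 1 and 14 members had an unadjusted p under 0.05 in that direction. The genes that rose, 854 on all arrays, numbered between 298 and 2391 when 1 array was left out, and those that fell, 765, between 365 and 1401; 1617 of the calls were shared without knockdown mouse 3. The rises were 1433 after median centring, 2351 with array weights, 1374 at an adjusted p under 0.1 and 407 with a minimum of 1.5-fold, and the falls were 1561 with array weights and 508 with the minimum. The array weights, whose estimation stopped before full convergence, gave knockdown mouse 3 a weight of 0.13 and wild type mouse 3 one of 5.12. The difference of Myb lay between -0.35 and -0.26 with 1 array left out (adjusted p between 0.00710 and 0.0967), was -0.23 after median centring (0.074), and kept its value of -0.30 without the trend (0.0662). Median centring moved the median of all genes to 0.092. With an estimated correlation the lists called up fell from 7 to 0 and those called down from 5 to 0. Camera takes no eBayes setting, so the lists have no value without the trend or with robust eBayes. Differences near 0 changed sign: with 1 array left out Eif2s3y lay between -0.25 and 0.0698 (without knockdown mouse 3) and Kdm5d between -0.23 and 0.14 (without knockdown mouse 3), and Kdm5d was 0.0142 after median centring and 0.0319 with array weights. Lists that were not called also changed direction, with these adjusted p: dendritic cell genes without knockdown mouse 3 (0.795) and with array weights (0.944); G2 and M phase genes without knockdown mouse 3 (0.682); kinase inhibitors and G1 cyclins with fry (0.847); Sprouty genes without wild type mouse 1 (0.829) and without knockdown mouse 3 (0.882), with a filter at 50% (0.664), with array weights (0.944) and with fry (0.883); adhesion genes without knockdown mouse 2 (0.899), without knockdown mouse 3 (0.944), without the filter (0.912) and with fry (0.125). With 1 array left out, whichever it was, the adjusted p lay between 0.0839 and 0.795 for the dendritic cell list, 0.0677 and 0.737 for G2 and M phase genes, 0.723 and 0.983 for Sprouty genes and 0.524 and 0.961 for adhesion genes. The cause was not tested for any of these.

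The replicate number as a block gave 746 rises and 726 falls, 7 lists up and 5 down, and Myb an adjusted p of 0.0318. Same-numbered mice had correlations of deviations from their group means of 0.29, -0.19 and -0.08. Those of different-numbered mice lay between -0.37 and 0.36. These values gave no sign that the numbers pair the mice, but with 3 mice per group they cannot exclude it.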

Other observations

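The tests on knockdown mouse 3 and on cell-type shares were chosen only after the result was seen, as were Car1, Malat1 and the genes and gene families named in the next paragraph. Fisher's exact test of the neighbourhood of Myb and the test of other splits of the arrays were planned. The comparison with windows around other genes was not part of that plan.

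The fatty acid desaturases Fads1, Fads2 and Fads3, neighbours on 1 chromosome, rose by 1.11 ± 0.09, 1.57 ± 0.12 and 1.53 ± 0.11 (SE). S100a4, a calcium-binding protein, rose by 1.73 ± 0.10. Among 322 families of genes that share a symbol stem, the mitochondrial ribosomal proteins Mrpl were higher by camera (48 genes, median 0.27, adjusted p = 8.7e-05), with 5 that rose, and the glutathione transferases Gstm were lower (6 genes, median -0.67, adjusted p = 0.00246), with 3 that fell. With an estimated correlation the adjusted p of both families was 0.993. Of 13767 probe sets without a single gene symbol, 7765 were brighter than the filter on dim genes. In a separate fit of these, 16 were higher and 23 lower, and 1348 had an unadjusted p under 0.05.

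Genes near Myb were called more often than others. Within 20 Mb of Myb, 25 of 127 genes were called, 11 higher and 14 lower, which is 19.7% against 11.5% elsewhere (odds ratio 1.88, 95% interval 1.16 to 2.94, Fisher's exact test, p = 0.00764). Of 1944 windows around other genes, which overlap each other, 13 had as large a share. If the knockdown comes from an altered allele at Myb, DNA of another strain carried along with it may account for part of the calls there. Perp, Ifngr1 and Myct1 are among these calls. The labels place all mice on the C57BL6 strain and do not describe an allele. Neighbouring genes that respond to Myb were not tested as an alternative.

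Knockdown mouse 3 stood apart from the other 2 knockdown mice. In it, 29 further erythroid genes had a median 0.21 above the mean of the other 2, where the central 95% of random lists ended at 0.16, and 22 of the 29 were higher; 24 of the 29 had a wild type mean above the median of all genes. Against the wild type mean, their medians were 0.13, -0.06 and 0.25 in knockdown mice 1, 2 and 3, and Car1, the brightest erythroid gene measured, lay at 11.53, 10.54 and 12.03 in them and at 11.23, 11.72 and 11.67 in wild type, so that mouse 2 was the farthest from the wild type for Car1. Small nucleolar RNAs had a median of -0.52 (7 of 49 higher), where the central 95% of random lists began at -0.18. Against the wild type mean their medians were 0.28, 0.38 and -0.29 in knockdown mice 1, 2 and 3. Malat1, a single noncoding RNA read beside them, lay at 10.25, 10.37 and 7.63 in knockdown mice 1, 2 and 3. In wild type it lay at 10.77, 10.92 and 10.86. Red-cell precursors in the sorted cells and a difference in RNA content or labelling may both contribute and are not separated here. The gate for CD11b-positive, lineage-low cells would remove such precursors if complete. The erythroid genes and the small nucleolar RNAs both lay outside the central 95% of random lists. Both comparisons rest on 1 mouse and cannot show a cause.

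Granule genes were lower while megakaryocyte and stem cell genes were higher. A lower share of neutrophil-lineage cells alone would raise the markers of every other cell type, but the mean shift was 1.01 for megakaryocyte genes and -1.37 for eosinophil genes, a gap of 2.39 ± 0.20 (SE over the 3 knockdown mice, 2.05 to 2.75). Camera had already called both lists when this gap was chosen, so the gap is not an independent test. Its SE takes the wild type mean as fixed and leaves out the spread of the wild type mice. On wild type arrays 1, 2 and 3 the eosinophil mean lay at 0.11, -0.18 and 0.07. The fall of the eosinophil genes was larger than that spread, though with an estimated correlation the list's adjusted p by camera was 0.307. The fall argues against a lower share of neutrophil-lineage cells as the whole cause only if those cells do not express these genes. That was not tested here. A change in the mixture of several cell types and a change within cells may each contribute and were not separated here.

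The 1619 genes called between the groups compare with 0 by limma in the highest of the other splits of the 6 arrays into 3 and 3, where up to 923 genes had an unadjusted p under 0.05, against 3578 in the real split. Every other split has wild type and knockdown mice on both sides. A difference between the groups then widens the spread within each side, so the 0 does not measure how many calls chance would give. Only 1 of the 10 splits, the real one, gave as many genes, and 10 splits are too few for a share under 0.05.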
